A study of Drosophila melanogaster with 2 samples.

How the data were processed

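RNA immunoprecipitation followed by sequencing (RIP-seq) recovers the RNA that comes down with a chosen protein and reads it on a sequencer. The 2 libraries described here came from S2R+ cells, an established adherent line of the Drosophila Schneider 2 lineage. Per the labels, the cells carried SF2 with C-terminal tags, listed as HA and FLAG, under the promoter of the metallothionein gene MtnA, which copper induces, and they were kept in 0.35 mM copper sulfate for 24 h. SF2 is the fly counterpart of the human splicing factor SRSF1, an SR protein. Both replicates carry the same label with both tags, and whether 1 tag or both were used in each library is not given in the sources used here, so the replicates may differ in tag. The labels name the antibody by its target, SF2, do not say whether it was directed at a tag, and give chemical fragmentation and sizes above 200 nt. Both libraries belonged to 1 group and were numbered biological replicates 1 and 2 by the submitters. The labels also point to a separate control experiment, which was not analysed here, so no enrichment over a control could be computed. All values therefore reflect RNA abundance and recovery in the precipitate together.

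The authors deposited 1 track of signal per library, which holds the coverage of all reads on the dm3 assembly scaled to library size, with 1 value per base and no separation of strands. Per the notes deposited with each track, it was made from the alignment file of that replicate alone, so replicates were not pooled. The aligner, its version, and the treatment of duplicate reads and of reads with several placements are not given in the sources used here. The scale was checked on the values. Each value was a whole multiple of the smallest value in its track, with a largest deviation of 9.31e-10, and signal times length summed to 50.0 times 1000000 in each track. Both facts fit reads of 50 aligned bases and a signal in reads per 1000000 placed reads (RPM), and both gave the same total, 7445986 reads in replicate 1 and 3889539 in replicate 2. A single read was worth 0.134 RPM at a base in replicate 1 and 0.257 in replicate 2. Signal is given in RPM at a base, or as its mean over the bases of a region. Reads in a region are its summed depth divided by 50.

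The tracks carry no gene names. The gene table at hand belonged to Release 6 of the genome, whose coordinates differ from dm3, and coordinates were not converted between builds. Regions are therefore named by sequence, start and end in dm3, counted from 1, and whether a region is exonic, intronic, untranslated or intergenic was not determined. The planned shares by feature class, exon over intron ratios and gene lists were not run for the same reason. The end of each sequence was taken as its last base covered in either library, which made 139.6 Mb over 14 sequences, of which 120.3 Mb lay on the 6 main arms (2L, 2R, 3L, 3R, 4 and X). The other 8 sequences are the mitochondrial genome (M), sequence not placed on a chromosome (U) and heterochromatic sequence assigned to a chromosome (names ending in Het).

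Signal was averaged over windows of 1 kb. Agreement between replicates was Pearson's r of log2(signal + 0.134), with a pseudocount of 1 read of the deeper library at a base, and Spearman's rho, over windows with signal in either replicate. Windows are not independent replicates and no p-value was attached to them. High-signal islands were runs of at least 10 times the mean signal of the main arms in the same replicate, with gaps of up to 50 bp joined, 50 bp or longer. Islands were shared when they overlapped by at least 1 base, and the chance overlap came from 100 random placements within each sequence. Without a control library, islands mark RNA with high signal and are not called binding sites. The rule for the regions named was fixed before the data were examined, as were the measures and the other settings tried, apart from the later choices given with them. It took the 15 windows with the highest mean signal on the main arms, the 5 highest on the other sequences, the 5 longest islands shared by both replicates, and the 5 windows furthest apart between replicates in each direction among those at 10 times the main-arm mean or more. The very deep stretches on U and XHet, the spread by signal level, the thinning of replicate 1 and the scaling to main-arm reads were chosen after the tracks had been examined. Values are means of the 2 libraries ± SD unless a replicate is named. With 2 libraries of 1 group, no test between conditions could be made. Intervals are 95% Wilson intervals for shares and exact binomial intervals for ratios of reads. They cover counting error only, and reads that are copies of one molecule make them too narrow. A count of 0 reads at a base allows up to 3 reads there, or 0.403 RPM in replicate 1 and 0.771 in replicate 2.

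Window length, pseudocount, the treatment of empty windows, a cap on the depth of the deepest covered bases, island threshold, joining, length and overlap were varied one at a time, and each replicate was left out in turn. The search for islands and for abrupt gaps in coverage was tested on a simulated chromosome with 200 introns and 2 libraries. The simulation stood for the comparison of the 2 replicates at their relative depths. At an exon depth of 80 reads in the deeper library, 100% of the introns were found at their exact ends in both libraries, and at 40 reads 62.5% were, with 0 false gaps at either depth. Reads were drawn evenly along the exons, and neither deletions nor sequence in which no read can be placed were simulated. The 0 false gaps therefore speak only to random sampling of reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.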

Results

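RNA that came down with the splicing factor SF2 was read in 2 libraries of copper-treated S2R+ cells. The libraries held 7445986 and 3889539 placed reads, so replicate 1 was 1.91 times as deep as replicate 2. The design implied the comparison of the replicates and a description of where in the genome the recovered RNA came from. Signal is in RPM, reads at a base per 1000000 placed reads, and all positions are in dm3.

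Most of the recovered reads fell outside the main chromosome arms, on sequence that is unplaced or heterochromatic. The unplaced sequence U took 46.0% ± 0.055 (SD, n = 2) of the reads, although it made up 7.20% of the reference length. The heterochromatic sequence of the X chromosome, XHet, took 7.29% ± 2.05 on 0.140% of the length. The 6 main arms, with 86.2% of the length, took 45.3% ± 2.02. The mitochondrial genome took 1.17% ± 0.038 of the reads, and the other 5 heterochromatic sequences together took 0.285% ± 0.013. The share on XHet was 5.84% (95% Wilson interval 5.82 to 5.86) in replicate 1 and 8.73% (8.71 to 8.76) in replicate 2, while those on U were 46.04% (46.00 to 46.07) and 45.96% (45.91 to 46.01). On each of the 6 main arms the share was lower in replicate 2, and together they held 46.7% of the reads in replicate 1 and 43.8% in replicate 2, a shift of -0.09 on the log2 scale. Shares of 1 total move together, so this is 1 shift and not 6 separate ones. These shares rest on few bases: with a cap that lowered the depth of the deepest 0.0998% of covered bases in replicate 1 and 0.0997% in replicate 2, the main arms held 97.2% of the signal.

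**Figure D1:**
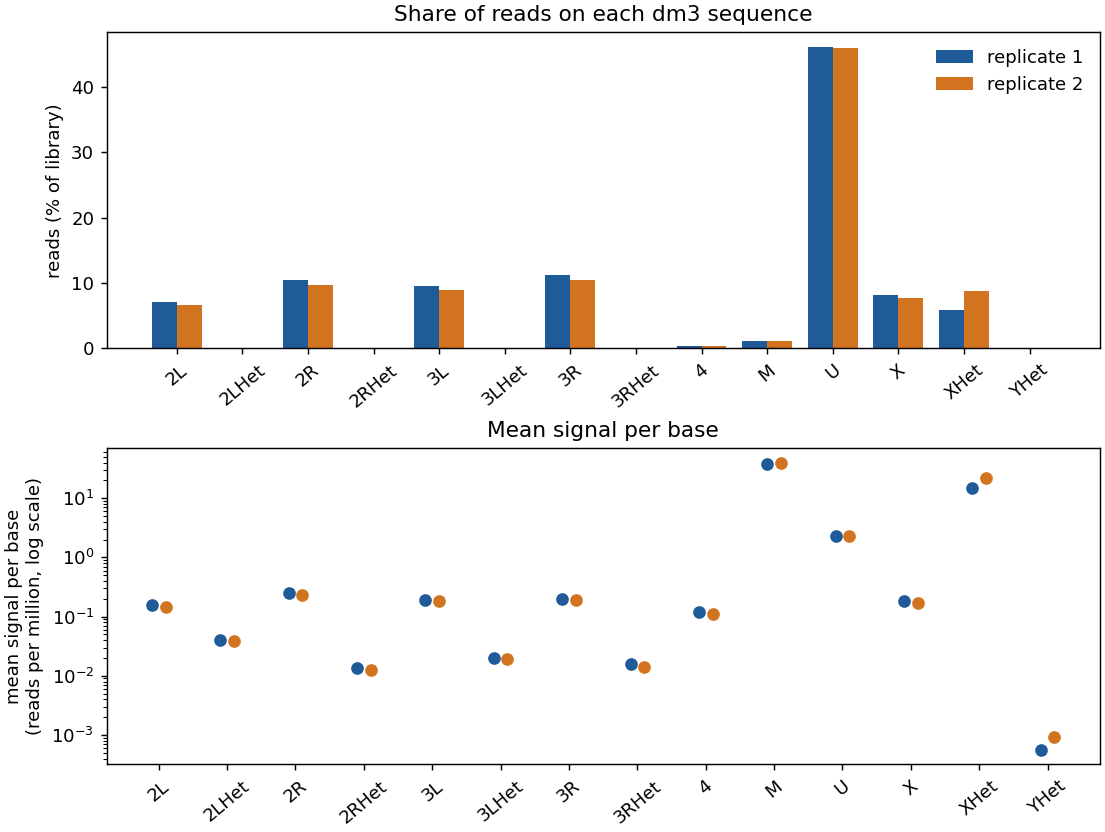
Upper panel, share of reads (percent of the library) on each dm3 sequence for replicates 1 and 2 (bars). Lower panel, mean signal per base in RPM on a log scale (points), highest on M at 39.1 ± 1.26 and lowest on YHet.

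The reads on U and XHet were concentrated in a few short stretches of high depth. The highest window, U 5727001 to 5728000, carried a mean signal of 12035 ± 167 RPM per base, 63984 times the mean of the main arms, from 1774740 reads in replicate 1 and 945410 in replicate 2. The next windows were U 9660001 to 9661000 at 2219 ± 76.0, U 6962001 to 6963000 at 2081 ± 332, U 9063001 to 9064000 at 1693 ± 74.1, and U 4571001 to 4572000 at 1590 ± 12.8. The stretches within these windows and on XHet were chosen for description after their values were seen. The covered stretch at U 6962855 to 6962939 was 85 bases long in both replicates and reached 45311 RPM in replicate 1 and 36110 in replicate 2. On XHet, the stretch 184667 to 184793 reached 24622 and 30591, and the stretch 191848 to 191990 reached 15272 and 35733. Covered stretches with a peak of at least 1000 RPM numbered 16 in replicate 1 and 17 in replicate 2, lay on U and XHet and on no other sequence, and held 51.2% and 54.0% of all reads. Each was between 60 and 284 bases long. What these stretches encode was not determined.

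**Figure D2:**
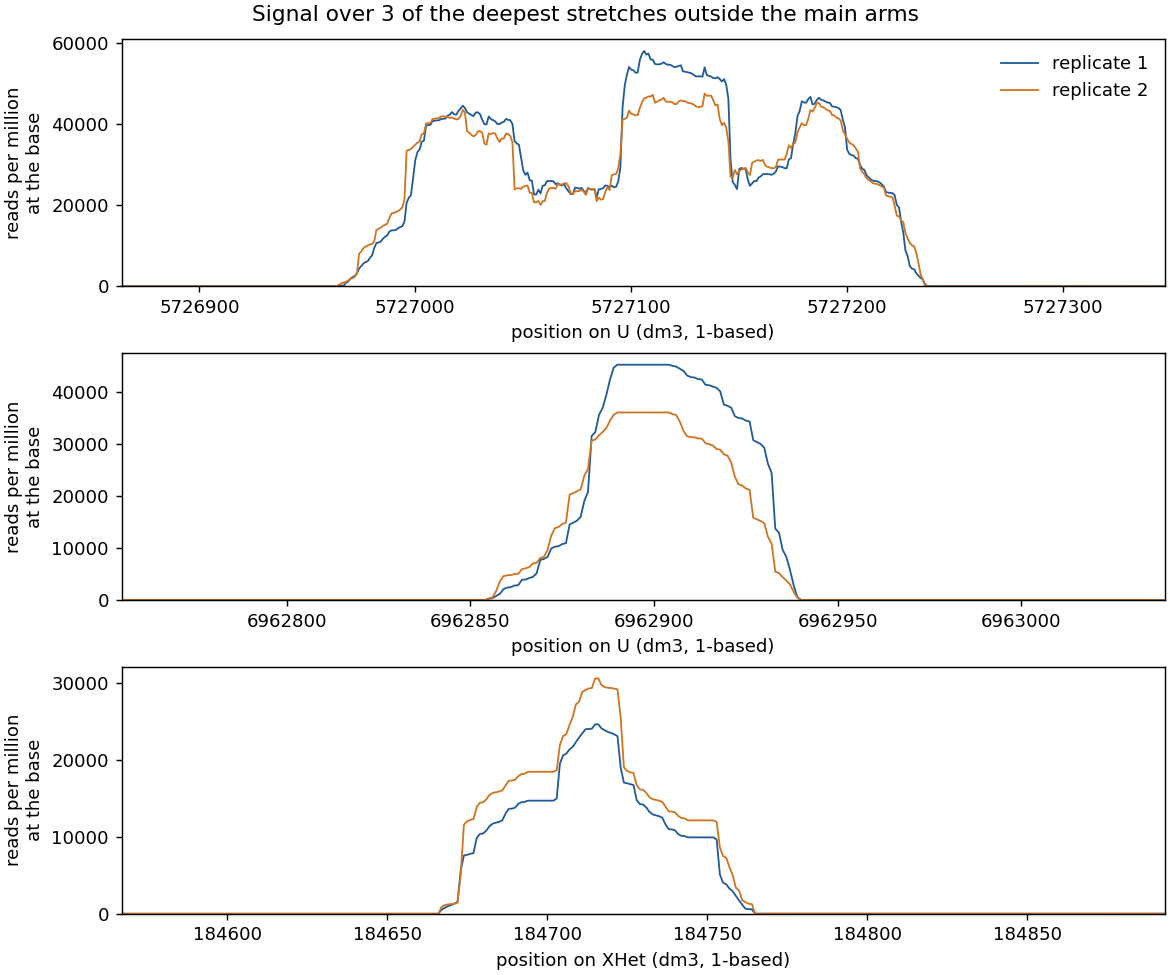
Depth at each base (RPM, linear axis from 0) along the 2 covered stretches of U and the 1 of XHet with the highest peaks of their sequence in replicate 1, by dm3 position, for replicates 1 and 2 (lines). Some stretches of U that are not shown had higher peaks than the one on XHet. Depth falls to near 0 on both sides of each stretch, for example of U 6962855 to 6962939.

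On the main arms, mean signal per base was highest on 2R and lowest on the small chromosome 4. The mean signal was 0.239 ± 0.011 RPM per base on 2R, 0.195 ± 0.008 on 3R, 0.187 ± 0.009 on 3L, 0.177 ± 0.008 on X, 0.150 ± 0.007 on 2L and 0.115 ± 0.007 on 4. Most of each SD is the fall of all arms together in replicate 2. As shares of main-arm reads, replicates 1 and 2 gave 22.28% and 22.28% on 2R and 23.95% and 24.02% on 3R. They gave 20.30% and 20.24% on 3L and 17.49% and 17.52% on X. Of the reads on the main arms, 22.3% came from 2R, which is 17.6% of their length, and 0.684% came from 4, which is 1.12%. Chromosome 4 carried 0.600 ± 0.010 of the signal per base of the large autosomal arms. The X carried 0.921 ± 0.001 of the signal per base of the large autosomal arms, but the median of its covered 1 kb windows was 1.02 times theirs, so that the direction depended on the measure. S2R+ cells are not euploid, and gene dose was not measured. Outside the arms, the 5 heterochromatic sequences other than XHet carried 0.016 ± 0.0007 RPM per base, against 0.188 ± 0.008 on the main arms. YHet held 28 reads in replicate 1 and 24 in replicate 2. The mitochondrial genome carried 39.1 ± 1.26.

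The 15 windows with the highest signal on the main arms lay in 10 stretches and held 4.94% of main-arm reads in replicate 1 and 4.95% in replicate 2. The window with the highest mean was 2R 2237001 to 2238000, at 127 ± 11.3 RPM per base, and its neighbour 2R 2236001 to 2237000 carried 65.5 ± 3.51. Both windows overlapped the island 2R 2236804 to 2237415, with the same first and last base in both replicates, a length of 612 bp and a mean depth of 332 RPM in replicate 1 and 297 in replicate 2. The windows 2R 7782001 to 7783000 and 2R 7781001 to 7782000 followed at 121 ± 14.3 and 96.0 ± 2.83, over an island of 1982 bp from 7781060 to 7783041 in both replicates. The 3 adjoining windows on 3L, from 3194001 to 3197000, carried 54.1 ± 1.07, 119 ± 6.12 and 94.8 ± 0.18, over an island that began at base 3194499 in both replicates and ended at 3197041 and 3197044. The window 3R 5455001 to 5456000 carried 85.1 ± 7.14 and held 2 islands separated by the bases between 5455337 and 5455430.

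The other windows of this set lay between 41.7 and 72.0 RPM per base. They were X 5325001 to 5326000 at 72.0 ± 0.48, 2R 18823001 to 18824000 at 60.4 ± 9.96, 3R 11071001 to 11072000 at 47.8 ± 0.64 with its neighbour 3R 11070001 to 11071000 at 41.7 ± 3.09, 3L 653001 to 654000 at 46.1 ± 0.95, 3R 5609001 to 5610000 at 44.6 ± 1.52 and 2L 21627001 to 21628000 at 43.6 ± 4.40. On 2L the signal fell into 2 islands whose inner ends, 21627757 and 21627842, were the same in both replicates. The last of the 15 windows by mean signal rested on 5888 reads in replicate 1 and 3415 in replicate 2. Within the island on 2R at 7781060, replicate 1 peaked at 302 RPM and replicate 2 at 200, while the mean depth of the whole island was 114 and 106.

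**Figure D3:**
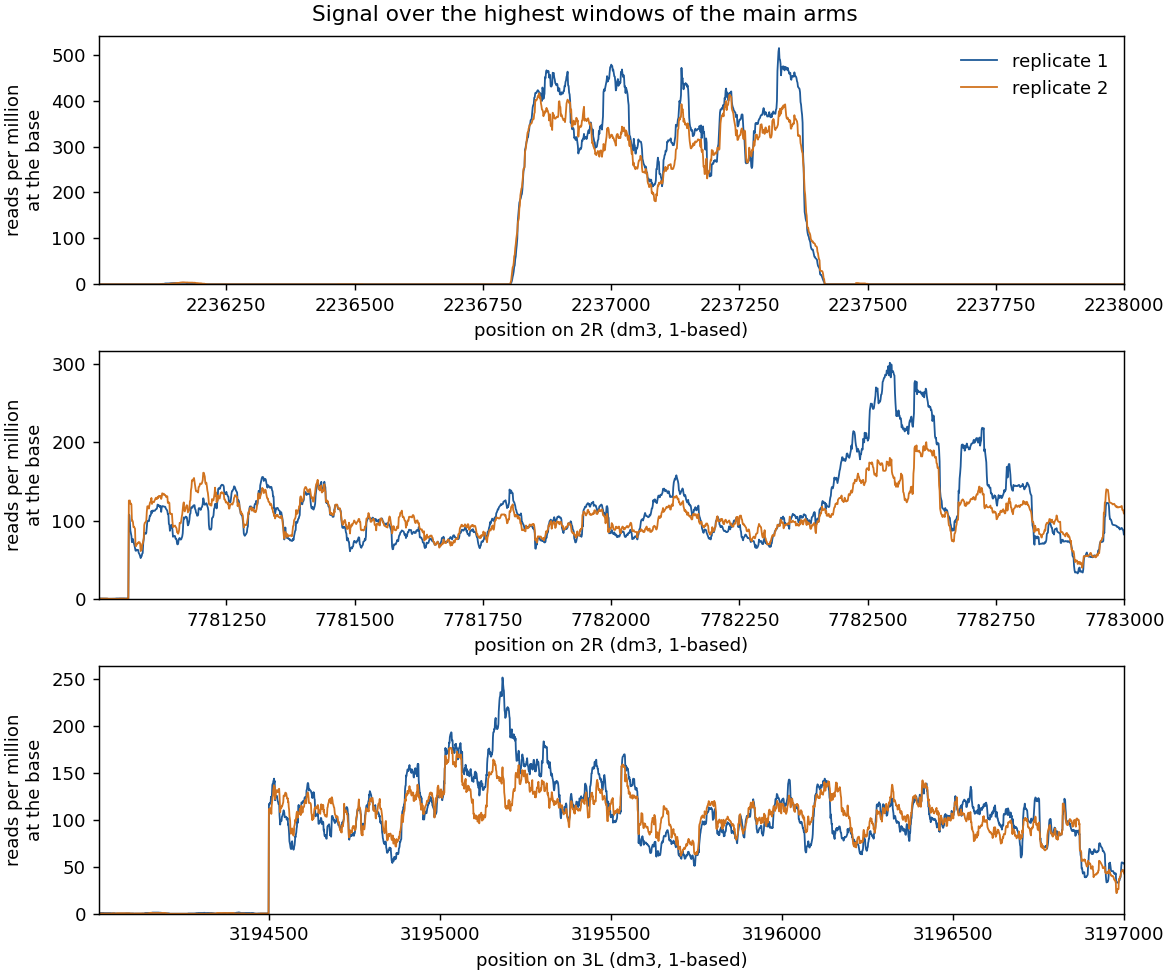
Depth at each base (RPM, linear axis from 0) over the 3 stretches that held the highest windows, on 2R and 3L, by dm3 position, for replicates 1 and 2 (lines). The island at 2R 2236804 to 2237415 has the same ends in both replicates, and the highest base of the island at 2R 7781060 reaches 302 in replicate 1 and 200 in replicate 2.

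Recovered RNA covered a small part of the genome, and most of the signal sat in a small share of the windows. Some depth was present at 13.0% of bases in replicate 1 and 10.8% in replicate 2. At the read number of replicate 2, replicate 1 would be expected to cover 10.8%, so the difference in breadth went with depth. The 1% of windows with the most signal held 73.2% ± 1.18 of it over all sequences, and the 1% of main-arm windows with the most held 39.8% ± 0.042 of the main-arm signal. At 10 times the main-arm mean, the threshold was 14.4 reads at a base in replicate 1 and 7.09 in replicate 2. Replicate 1 had 10903 islands with a median length of 150 bp and replicate 2 had 11465 with a median of 134 bp. These differences in number and length were not separated from the difference in depth. Over all sequences the islands took 2.00% and 1.93% of the reference length and held 83.3% and 84.0% of all reads. Those on the main arms held 64.6% and 63.8% of the main-arm reads. Of the islands on all sequences, 77.66% in replicate 1 and 77.71% in replicate 2 overlapped an island of the other, against at most 4.40% and 4.06% in any of 100 random placements. Random placements could also fall on bases without any depth. Libraries of the same cell line that cover the same RNA would exceed them, so this outcome was fixed in advance. When at least 50% of each island had to overlap, 55.6% and 52.8% were shared. Among the main arms, islands were densest on 2R, with 108 ± 4.58 per Mb, and least dense on 4, with 60.3 in both replicates. The number of islands depended on the threshold, with a mean of 4707 at 20 times the main-arm mean and 23407 at 5 times. Replicates 1 and 2 had 4761 and 4653 at 20 times, and 21364 and 25449 at 5 times. Which replicate had more islands therefore also depended on the threshold.

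The 5 longest islands shared by the replicates all lay on the main arms. The longest, 2L 3060230 to 3066957, measured 6728 bp in both replicates and carried 8.39 ± 0.19 RPM per base. The next, X 10359916 to 10365571, shared 5656 bp and carried 9.87 ± 0.008. The other islands, all on 3L, followed, from 19875754 to 19881204 (5451 bp, 5.09 ± 0.020), from 225726 to 230913 (5188 bp, 8.47 ± 0.83) and from 1784907 to 1788957 (4051 bp, 9.56 ± 0.14). Shared pieces of 1000 bp or longer numbered 298.

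The replicates ordered the windows of the main arms much alike, and those of U and of 5 heterochromatic sequences less so. Over 50521 windows with signal in either library, Pearson's r of log2 signal was 0.987 and Spearman's rho was 0.908. On the single main arms, r lay between 0.973 on 4 and 0.987 on 2R, and rho between 0.868 on 4 and 0.920 on 3R. Mitochondrial windows gave r = 0.989 and rho = 0.986, and windows on XHet gave 0.988 and 0.852. On U, r was 0.990 but rho was 0.717. Of the 548 windows of U with signal, 41 reached 10 times the main-arm mean. Some depth was present at 0.586% ± 0.088 of its bases, so its mean of 2.29 RPM per base does not describe most of its windows. On the other 5 heterochromatic sequences rho was lower, at 0.550 on 2LHet, 0.526 on 2RHet, 0.487 on 3LHet, 0.476 on 3RHet and 0.408 over the 8 windows of YHet. There r was 0.976, 0.963, 0.982, 0.979 and 0.862 in the same order. These sequences averaged 0.016 RPM per base, where 1 read in a 1 kb window gives 0.007 in replicate 1 and 0.013 in replicate 2. Of 139565 windows, 36541 had signal in both replicates, 9753 in replicate 1 alone and 4227 in replicate 2 alone. Windows seen in 1 library alone held a median of 1 read, and for windows at that level presence against absence was not resolvable at this depth.

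**Figure D4:**
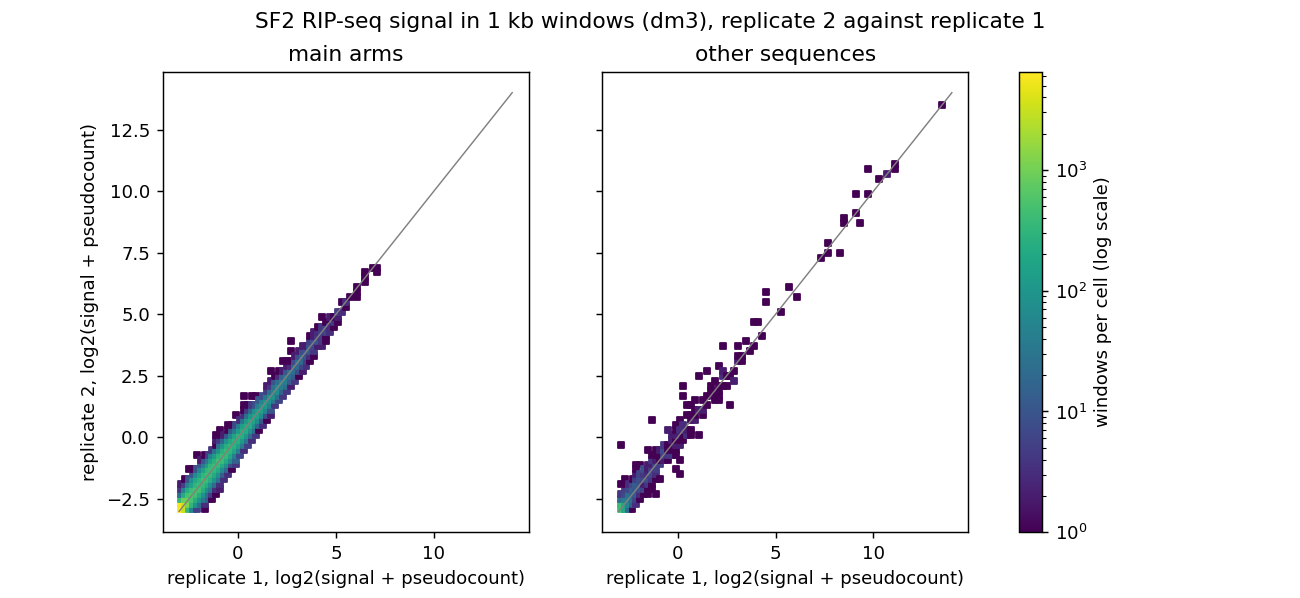
Mean signal of each 1 kb window with signal in either replicate, in replicate 2 against replicate 1, as log2(signal per base + 0.134), on the main arms (left) and the other sequences (right). Colour gives the number of windows per cell on a log scale and the line marks equal signal.

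The spread between the libraries shrank with signal on the main arms. Ratios here were scaled to main-arm reads. Among main-arm windows with signal in both libraries, the log2 ratio had an SD of 1.10 below the main-arm mean, where windows held a median of 6 and 3 reads. The SD was 0.36 from 1 to 10 times the mean, 0.22 from 10 to 100 times, and 0.19 in the 64 windows above 100 times. The squared deviation averaged 1.48, 4.93 and 24.2 times that expected from counting reads in the last 3 classes. Separate samples are expected to exceed counting error, and the comparison served to check whether 1 library had been deposited under both labels. The tracks were counted as 2 libraries. On this scale, differences of more than 2-fold were found in 6102 of 17641 windows below the mean (34.6%), in 191 of 15616 from 1 to 10 times the mean (1.22%), in 5 of 2267 windows from 10 to 100 times the mean and in 0 of the 64 above.

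Among the 2404 windows at 10 times the main-arm mean or more, those furthest apart between replicates were often on U. As deposited, replicate 2 over replicate 1 was 3.90 (exact binomial 95% interval 3.23 to 4.71) at U 9882001 to 9883000, 2.89 (2.36 to 3.54) at U 9400001 to 9401000, 2.88 (2.48 to 3.35) at U 3558001 to 3559000 and 2.67 (2.56 to 2.79) at U 9836001 to 9837000. The only main-arm window among these 5 was X 658001 to 659000, at 2.85 (2.33 to 3.52), from 158 reads in replicate 1 and 236 in replicate 2. In the other direction the ratio was 0.350 (0.295 to 0.412) at U 9455001 to 9456000 and 0.571 (0.560 to 0.582) at U 8595001 to 8596000. It was 0.572 (0.470 to 0.699) at 2L 8089001 to 8090000, 0.576 (0.471 to 0.699) at X 3600001 to 3601000 and 0.595 (0.492 to 0.714) at 3R 24151001 to 24152000. Scaling to main-arm reads shifts every log2 ratio by the same amount, set by the log2 difference of -0.09 in main-arm reads between the libraries. This is too small to change the direction of any of these 10 windows, so their unchanged direction says nothing about stability. They were selected as the most different of the 2404, which the intervals do not take into account, and compare 2 libraries of 1 group. As deposited, without scaling to main-arm reads, 4 of the 2331 windows at 10 times the main-arm mean or more on the main arms and 9 of the 73 elsewhere differed by more than 2-fold.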

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

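Thinning, scaling to main-arm reads, the definition and extent of deep stretches, all settings of the gaps and leaving out a replicate for the number of islands were chosen after seeing the data. Of 63 alternative values other than those from leaving out a replicate, 19 stayed within 1 SD of the replicates, the 95% Wilson interval for the share of matched deep stretches, 0.005 for r and rho, 0.5 for a log2 ratio between replicates or 1.5 times for a count, 44 moved and 0 changed the sign of a ratio between replicates. The ratios between replicates were those of the 10 windows furthest apart, all shifted by the same amount on scaling to main-arm reads. That amount is well below 0.5 and below each of these ratios on the log2 scale. That these 10 values stayed and kept their sign was therefore fixed in advance. Another 68 values came from leaving out a replicate, which says nothing about stability here, since each of 2 replicates lies 0.707 SD from their mean. Pearson's r moved from 0.987 to 0.900 with 100 bp windows, 0.997 with 10 kb windows and 0.978 above the median signal. Spearman's rho moved from 0.908 to 0.806, 0.968 and 0.962 in these settings, to 0.865 with empty windows included and to 0.914 on the main arms only. Breadth moved from 11.9% of bases to 6.58% above the second smallest value and 7.51% above the genome-wide mean. The signal per base of X over autosomes moved from 0.921 to 0.939 under the cap on the deepest bases and to 1.02 as a median over covered windows, on the other side of 1, and the cause was not tested. The top 1% of windows held 76.5% of the signal with 100 bp windows and 39.8% on the main arms only. The cap moved the share of the main arms from 45.3% to 97.2%, of U from 46.0% to 1.23%, of XHet from 7.29% to 0.215% and of M from 1.17% to 0.769%, since by construction it lowers the deepest bases. The mean number of islands moved from 11184 to 4707 at 20 times the mean, 23407 at 5 times, 6484 with gaps up to 200 bp joined and 7437 at 100 bp or longer. The shared percentage moved from 77.7% to 79.9%, 76.7%, 80.8% and 80.9% in these settings, to 74.6% with no gap joined and to 54.2% when 50% of each island had to overlap. The intron-like gaps moved from 933 to 2523 with flanks of at least 10 reads and 326 with at least 40. Shares by feature class, exon over intron ratios and gene lists were not run. Where windows held a median of 6 and 3 reads, depth did not allow differences between the libraries to be told from counting error.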

Other observations

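The definitions of gaps, deep stretches and their extent, the 3 tests on deep stretches, the test of moved gaps and the test of pairs within libraries were chosen after related values had been seen. The tests of pairs between libraries and of read bases beside gaps were set before their results were seen. Coverage of the main arms was interrupted at fixed bases. A gap was counted where depth fell at 1 base to at most 20% of a flank of at least 20 reads and rose in the same way 40 to 2000 bases later, with no base between above 50% of the lower flank. Replicate 1 had 2574 such gaps and replicate 2, with fewer reads, had 953, of which 933, or 97.9%, had both ends at the same bases in replicate 1. The most frequent length was 62 bp, the median was 86 bp, and 392 of the 933 gaps measured 55 to 75 bp. By arm, 2R held 11.4 gaps per Mb, 3R 8.46, 3L 7.38, X 6.73, 2L 5.31 and 4 had 3 gaps in all.

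Little depth remained inside these gaps, as their definition requires. The mean inside was 0.831% of the flanking depth in replicate 1 and 0.835% in replicate 2, and 308 gaps held no signal in either library. The 436 gaps of 40 to 79 bp averaged 0.642% and 0.678%, and the 155 gaps of 500 to 2000 bp averaged 1.26% and 1.22%. Allowing a drop to 50% of the flank gave 950 gaps with means of 0.929% and 0.962%. Depth above 5% of the flanks in both libraries was found in 17 gaps. The highest mean was at X 519139 to 519198, chosen after its values were seen, with 10.8% and 21.1% beside flanks of 45.5 and 22.5 reads.

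A candidate explanation of the gaps is that they are introns removed by splicing, with reads aligned across them. Split reads leave part of their 50 bases on either side. Of stretches bordering an empty gap, 1.97% (95% Wilson interval 1.17 to 3.27) of 712 in replicate 1 and 1.16% (0.63 to 2.12) of 863 in replicate 2 held a multiple of 50 read bases. Over both libraries this was 1.52% of 1575, in which a gap can be counted in each library. Of other stretches of at least 20 reads, 26.5% and 31.1% held such a multiple. At sequence in which no read can be placed, whole reads would end and leave multiples of 50. The low share argues against this only for stretches in which no read is split elsewhere. A split elsewhere also breaks the multiple, so such sequence within a spliced transcript is not excluded. Moving the gaps of replicate 1 by 1 to 10 bases matched at most 0 gaps of replicate 2. This cannot decide on coincidence of edges, since 933 of the 953 gaps of replicate 2 already matched unmoved. Gaps of 1 library do not overlap and measured at least 51 bp, so a matched gap could not match again after so small a move. Deletions in the genome of the cell line, crossed by gapped alignments, were not tested and stay open, as the tracks hold no sequence and no strand.

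The deep, narrow stretches on U and XHet may be the parts of a repeated sequence at which a read can be placed in 1 position only, since reads of 50 bases that share a base span at most 99. Counting bases at 1% of the peak or more, 75.8% of the deep stretches of both libraries spanned no more than that, against 1 of 16 in replicate 1 and 2 of 17 in replicate 2 of the main-arm stretches with the highest peaks. This extent was chosen after the lengths were seen, the share was 81.8% at 10% of the peak but 27.3% over all covered bases, and the deepest stretch, U 5726964 to 5727247, spanned 269 and 270 bases, so this stays open. Of the 16 stretches of replicate 1, 100% recurred in replicate 2 with both ends of that extent within 5 bases, and 87.5% by the ends of all covered bases. This cannot decide on amplification of a few molecules in each library. If reads can be placed only at these positions, which stays open, the ends would match whichever molecules were amplified. Ribosomal RNA, whose genes are repeated in heterochromatin, is a candidate source of these stretches, which held a mean of 52.6% of the reads, but no dm3 sequence was used here, and no biological explanation was tested.

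Reads at exactly the same position were more frequent in the deeper library: among isolated stretches of 2 overlapping reads, both lay at 1 position in 23.8% (95% Wilson interval 23.2 to 24.5) of 15045 in replicate 1 and 6.92% (6.52 to 7.35) of 14658 in replicate 2, where 1.01% would follow with no preference. Overlapping lone reads of the 2 libraries lay at 1 position in 2.62% (2.29 to 2.99) of 8142 pairs, which argues against fragment ends fixed by sequence as the whole cause. Amplification copies kept in the alignments may account for the rest, but this stays open, since that explanation alone called for a share between libraries near 1.01% and the share was higher. No biological explanation was tested.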
